A study of Homo sapiens with 11 samples.

How the data were processed

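RNA was sequenced from MCF7 cells, an established line derived from a breast adenocarcinoma, in 11 libraries that form 4 groups. Cells were wild type for RB1, the gene of the retinoblastoma protein, or carried an RB1 deletion. Each genotype received birinapant at 500 nM or the solvent DMSO, and RNA was taken after 48 h, per the series design text. Birinapant is a SMAC mimetic, a compound that binds inhibitor of apoptosis (IAP) proteins. Wild-type DMSO had 2 libraries and each of the other 3 groups had 3, with groups and replicate numbers taken from the sample titles. The titles call the replicates biological, but how the cultures were separated is not given, so p-values measure only the spread between these samples.

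Per the labels' protocols, every library was prepared with the same stranded total RNA kit. Reads were aligned with STAR and quantified per isoform with RSEM on GRCh37, per the submitters' processing notes. Tool versions, the annotation release and the strand setting are not given in the sources used here. Per the file headers, each deposited file lists an RSEM expected count, TPM, FPKM, an effective length and the percent of a gene's abundance held by each isoform. The deposited expected counts are estimated read counts without normalization. The authors' TPM values share 1 total in all libraries, and the authors' FPKM values were used only for their sum per library. The deposited isoform percent was used only for RB1.

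Each file listed 196354 isoforms of 57773 Ensembl genes, and 52338 gene identifiers (90.6%) matched a symbol in the reference tables. Gene types came by identifier from a GENCODE annotation of a later build than the authors', so no coordinates are printed. Expected counts were summed per gene and rounded to whole numbers. Totals were 7775552 to 10854499 per wild-type library and 21041236 to 26217669 per RB1-deletion library. A gene at 0 in every library of a group received a floor of 3 counts per library, which covers counting error only.

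The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM normalization and the filterByExpr filter. A single fit held all 4 groups, so that the 2 wild-type DMSO libraries shared the estimate of spread with the others, and 16572 genes were tested. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Levels are CPM scaled by TMM, and log2 fold changes carry the standard error (SE) derived from the test statistic. The 5 contrasts were birinapant against DMSO in each genotype, RB1 deletion against wild type in each treatment, and the difference between the drug responses.

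Before the data were examined, 26 gene lists were fixed with 845 members, of which 27 had no matching gene identifier. Lists with at least 5 tested members were tested with limma's camera (limma 3.58.1) at a preset correlation of 0.01, on log2 CPM with a prior count of 2. Adjustment was by Benjamini-Hochberg over the lists of a contrast. Beside this stand camera with an estimated correlation, limma's fry, and the number of members called when p was adjusted over the list alone. The rule for named genes was also fixed beforehand. It takes RB1, BIRC2, BIRC3 and XIAP always. It adds the 8 rising and 8 falling genes with the largest fold change among called genes with at least 5 CPM in the higher group and no overlap between libraries. For a discussed list it adds the first 2 members and up to 4 called members with the largest change. Genes without a symbol, small RNAs and placeholder symbols were left out of the rule for the largest changes.

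The procedure was tested on simulated counts in which 200 genes were changed. These counts used the real library sizes, each gene's mean over all libraries, and 1 spread per gene shared by all libraries. Neither a length trend nor a separate spread per genotype was simulated, so the shares below do not cover these. For the wild-type drug contrast, 22.4%, 61.2% and 77.3% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, and 7.8% of calls were false. For the RB1-deletion drug contrast the shares were 44.8%, 71.6% and 90.9%, with 9.2% false calls. Replicate pairs were compared by a chi-square test of their counts. Its value per degree of freedom ran from 3.79 to 42.46, so no pair was treated as repeated deposits of 1 library.

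Alternatives fixed beforehand were DESeq2 size factors, upper-quartile factors, no filter, a filter of 1 CPM in 3 libraries, DESeq2's Wald test (DESeq2 1.42.0), limma-trend on log2(TPM + 0.5), an effective length offset, a fit of the compared groups only, the replicate number as a block, leaving out the 10 most abundant genes, a 2-fold threshold and leaving out each library. Alternatives chosen after seeing the data were protein-coding genes only, removal of a length trend per library, thinning of the RB1-deletion libraries to wild-type depth, voom weights per genotype, and leaving out wild-type birinapant libraries 1 and 3. Figures were drawn with matplotlib 3.10.9.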

Results

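Transcripts were measured by RNA sequencing in MCF7 cells with wild-type RB1 or an RB1 deletion, after 48 h in DMSO or 500 nM birinapant. There were 2 wild-type DMSO libraries and 3 in each other group. Total expected counts were 7775552 to 10854499 per wild-type library and 21041236 to 26217669 per RB1-deletion library.

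The RNA content of the libraries separated by genotype. Protein-coding genes held 63.7% to 83.01% of counts in wild-type libraries and 95.52% to 95.71% in RB1-deletion libraries. Small non-coding RNAs such as snRNAs and snoRNAs held 2.85% to 8.1% of wild-type counts and 0.0% of RB1-deletion counts, to the digits given. Replication-dependent histone genes, whose mRNAs end without a poly(A) tail, held 0.858% to 1.341% against 0.052% to 0.056%. Within wild type, the protein-coding share was 63.7% and 68.87% in the DMSO libraries, and 82.36%, 72.51% and 83.01% in birinapant libraries 1, 2 and 3. The labels name 1 kit for all libraries, while their library identifier series splits exactly by genotype. No batch holds both genotypes, so library series and genotype cannot be told apart in any comparison between them. The biological coefficient of variation was 0.18 in wild type and 0.061 in RB1 deletion.

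**Figure D1:**
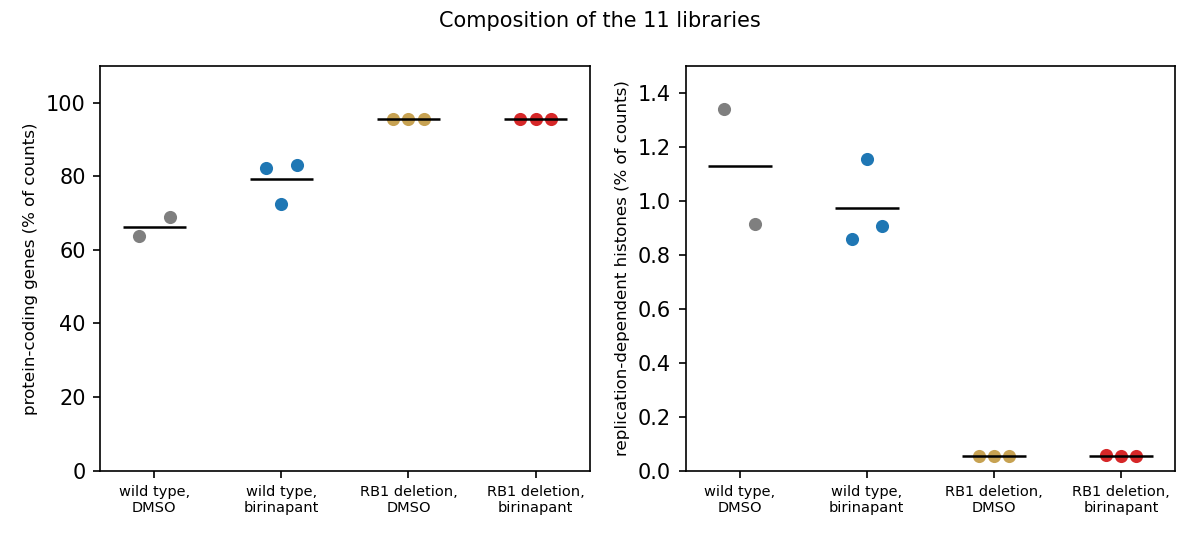
Share of counts in each of the 11 libraries, in percent, held by protein-coding genes and by replication-dependent histone genes, with libraries grouped by genotype and treatment. Protein-coding genes held 95.52% to 95.71% in RB1-deletion libraries and 63.7% to 83.01% in wild-type libraries.

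RB1 RNA (ENSG00000139687) was present in every library. Its level was 46.9 ± 2.36 CPM (SD, n = 2) in wild-type DMSO and 56.7 ± 9.53 CPM (SD, n = 3) in wild-type birinapant. It was 28.1 ± 1.63 CPM and 26 ± 2.08 CPM (SD, n = 3 each) in RB1-deletion DMSO and birinapant. RB1 was thus lower by -0.74 log2 (SE 0.13; edgeR adjusted p = 0.00096) in DMSO and by -1.13 log2 (SE 0.12; edgeR adjusted p = 1.82e-05) in birinapant. On the TPM scale the order turned, with 3.51 and 3.08 times the wild-type DMSO level in the RB1-deletion groups. There RB1 stood at 1.71 log2 in DMSO, below the median of all genes on that scale, 2.03 log2. The 4840-base transcript ENST00000267163 held 95.12% and 77.44% of RB1 abundance in the wild-type groups and 90.41% and 93.16% in the RB1-deletion groups. The tables give no exon coverage, so RNA from outside a deleted part would be counted, and these levels do not check the deletion.

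Birinapant in RB1-deletion cells raised NF-kB target genes and interferon-stimulated genes. BIRC3 (ENSG00000023445), which encodes the IAP protein cIAP2, rose from 0.657 ± 0.16 to 7.53 ± 1.65 CPM (SD, n = 3 each; log2 fold change 3.50, SE 0.23). TNFAIP3 (ENSG00000118503), a ubiquitin-editing brake on NF-kB, rose from 2.11 ± 0.183 to 21.4 ± 3.52 CPM (SD, n = 3 each; log2 fold change 3.34, SE 0.15). The other IAP genes in the named set stayed within their error, with log2 fold changes of 0.06 for BIRC2 (SE 0.11) and -0.06 for XIAP (SE 0.14). In all, 56 genes were called higher and none lower among 16572 tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment. Of the 56, 39 rose at least 2-fold. At an unadjusted p under 0.05 there were 676 genes in both directions.

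Of the 56 genes, 15 belonged to an NF-kB list, 18 to the interferon list and 18 to none of the 26 lists. In the list of NF-kB targets 12 of 32 members rose and none fell, and 20 rose with p adjusted over the list alone. They included UBD, a ubiquitin-like modifier (4.20 log2), TNF (3.68), the adhesion molecule ICAM1 (2.35, SE 0.12) and NFKBIA, which encodes the inhibitor IkB-alpha (1.25, SE 0.10). UBD and TNF were sparse in DMSO, with 4 and 7 counts over 3 libraries. In the list of non-canonical NF-kB genes 4 of 10 rose, and 5 with p adjusted over the list alone. These were BIRC3, the subunit genes RELB (2.65, SE 0.17) and NFKB2 (1.2, SE 0.08), and MAP3K14, which encodes the kinase NIK (1.83, SE 0.10). In the interferon list 18 of 48 rose, and 39 with p adjusted over the list alone. IFIT1 rose by 2.36 (SE 0.20), IFIT3 by 2.33 (SE 0.22), IFIT2 by 2.27 (SE 0.22) and OASL by 1.80 (SE 0.17). The median log2 fold change was 0.70 over the interferon list, 0.69 over the NF-kB targets and 0.32 over the non-canonical list. Their camera adjusted p-values were 2.96e-79, 3.79e-46 and 2.55e-18, and each was 0.00437 with an estimated correlation.

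**Figure D2:**
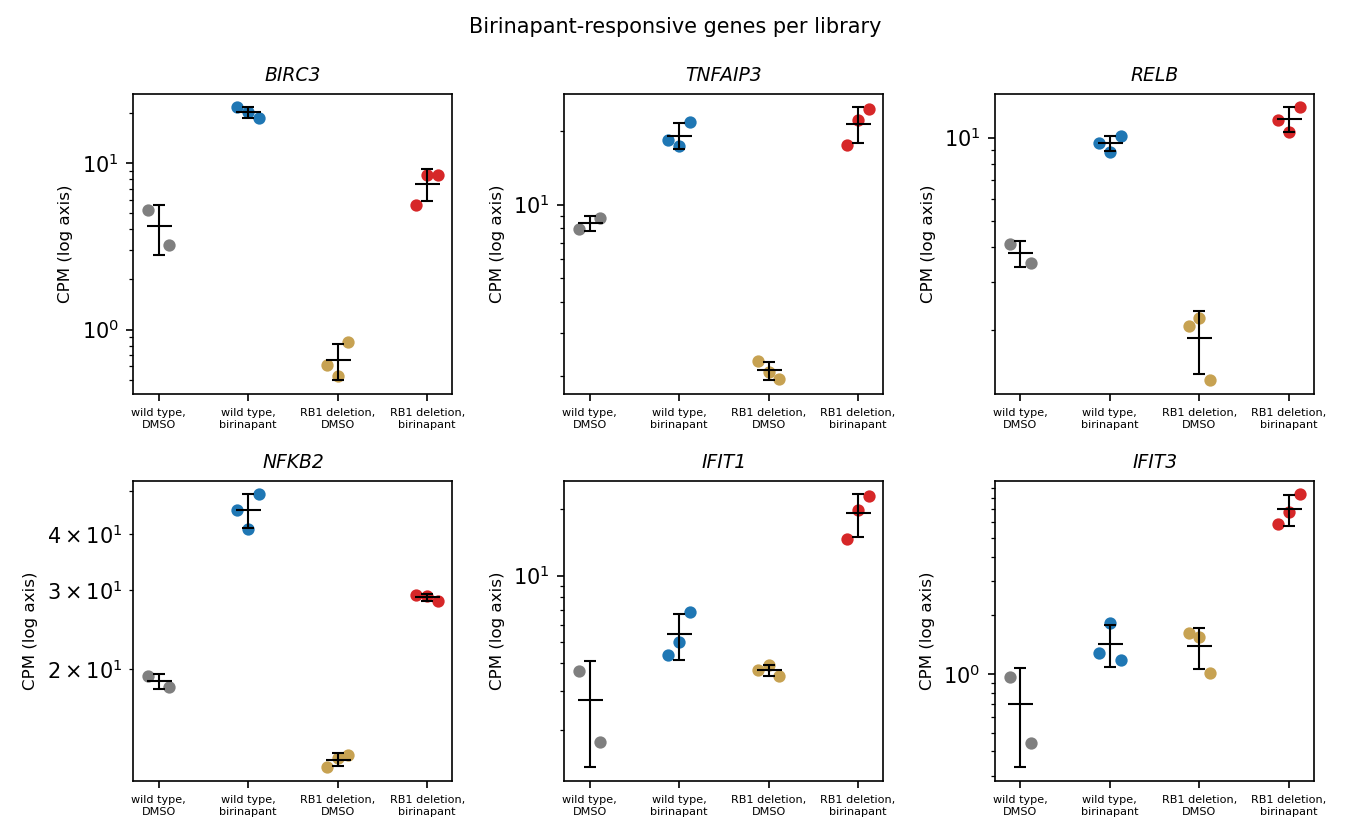
Level of BIRC3, TNFAIP3, RELB, NFKB2, IFIT1 and IFIT3 in CPM on a log axis, with 1 point per library and a bar at the group mean. In RB1-deletion libraries BIRC3 rose from a mean of 0.657 to 7.53 CPM, and in wild-type libraries from 4.22 to 20.3 CPM.

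Smaller shifts reached other lists in the RB1-deletion cells. In the antigen presentation list 1 of 25 members rose, and 5 with p adjusted over the list alone. This was TAP1, a peptide transporter (1.18, SE 0.15), while HLA-A and B2M had log2 fold changes of 0.24 and 0.28 and did not pass. The list's camera adjusted p was 3.31e-10, and the adjusted p was 0.102 with an estimated correlation. Among immediate early genes 2 of 24 rose, ATF3 (1.14, SE 0.15) and JUNB (0.71, SE 0.08), and 8 with p adjusted over the list alone. That list had a camera adjusted p of 3.95e-13, with an adjusted p of 0.0707 with an estimated correlation. In the unfolded protein and ATF4 list 2 of 27 rose, ATF3 and PPP1R15A (0.98, SE 0.13), and 6 with p adjusted over the list alone. Its camera adjusted p was 5.14e-11, or adjusted p = 0.0333 with an estimated correlation. In the IAP list BIRC3 alone rose among 14 members, 3 with p adjusted over the list alone (camera adjusted p = 3.76e-05; adjusted p = 0.0286 with an estimated correlation). None of 40 estrogen receptor targets passed over all genes, while 5 fell and 1 rose with p adjusted over the list alone. Their median was -0.07 (camera adjusted p = 0.00849; adjusted p = 0.0452 with an estimated correlation). ESR1, the receptor gene itself, had a log2 fold change of -0.13 (SE 0.11) and did not pass. TNF alone rose among 20 death receptor genes, 2 with p adjusted over the list alone (camera adjusted p = 0.0209; adjusted p = 0.0773 with an estimated correlation). Camera also called ribosomal proteins, p53 targets, the BCL2 family and oxidative phosphorylation higher, and DNA damage and cholesterol genes lower. None of their members passed over all genes, and none of these lists passed with an estimated correlation. The ribosomal protein list was called at a median of only 0.09 (camera adjusted p = 0.00047). With only the RB1-deletion libraries in the fit 232 genes were called, 201 higher and 31 lower, and DESeq2 called 121; all 56 genes were among both. Limma-trend on TPM called 31 and put BIRC3 at 1.77.

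In wild-type cells, birinapant raised the same 4 non-canonical NF-kB genes. BIRC3 rose from 4.22 ± 1.4 (SD, n = 2) to 20.3 ± 1.41 CPM (SD, n = 3), a log2 fold change of 2.26 (SE 0.25; edgeR adjusted p = 0.00174). MAP3K14 rose by 1.89 (SE 0.15), RELB by 1.32 (SE 0.23) and NFKB2 by 1.26 (SE 0.11). TNFAIP3 rose by 1.19 (SE 0.18; edgeR adjusted p = 0.00734) and UBD by 4.43 (SE 0.58), the latter from 4 counts over 2 libraries. BIRC2 and XIAP had log2 fold changes of 0.16 (SE 0.15) and 0.17 (SE 0.16) and did not pass.

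Of the non-canonical NF-kB list 5 of 10 members rose, 7 with p adjusted over the list alone, with a median of 0.59. Its camera adjusted p was 1.06e-05, and the adjusted p was 0.299 with an estimated correlation. Of the NF-kB targets 11 of 32 rose, 12 with p adjusted over the list alone, with a median of 0.44 (camera adjusted p = 4.38e-05; adjusted p = 0.672 with an estimated correlation). In the interferon list 10 of 48 rose and 3 fell, or 12 and 5 with p adjusted over the list alone (camera adjusted p = 0.017; adjusted p = 0.784 with an estimated correlation). That list did not pass without wild-type DMSO library 2 (camera adjusted p = 0.362) or birinapant library 2 (camera adjusted p = 0.0583). OASL rose by 1.55 (SE 0.32) and STAT1 by 0.40 (SE 0.12), ISG20 changed by -0.94 (SE 0.18), and IFIT1 at 0.97 (SE 0.35) did not pass (edgeR adjusted p = 0.0824). STAT1 lost its call in 9 of the 11 fits that left out a library (edgeR adjusted p up to 0.143), OASL in 1 (up to 0.0521), TRAF2 in 2 (up to 0.074) and USP19 in 3 (up to 0.105). In the IAP list 4 of 14 rose, also 4 with p adjusted over the list alone: BIRC3, TRAF3 (0.88, SE 0.12), TRAF2 (0.51, SE 0.12) and USP19 (0.40, SE 0.11). The IAP list did not pass (camera adjusted p = 0.112). Camera also called E2F targets and unfolded protein genes higher (camera adjusted p = 0.0214 each) and replication-dependent histones lower (camera adjusted p = 0.0011). With an estimated correlation their adjusted p-values were 0.881, 0.672 and 0.784.

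Genes of the translation and respiration machinery were lower in treated wild-type libraries. Of 59 ribosomal protein genes 48 fell, 55 with p adjusted over the list alone, and the median was -0.86. Only 3 were called without wild-type birinapant library 1, 4 without library 3 and 9 without DMSO library 1, where the median was -0.48; without DMSO library 2 it was -1.15. The camera adjusted p was 1.12e-17, but the adjusted p was 0.672 with an estimated correlation. RPL34 changed by -1.30 (SE 0.25) and RPS15A by -1.23 (SE 0.25), while RPL3 and RPL4, at -0.26 and -0.36, did not pass. On the TPM scale, which moved the median of all genes to 0.61, they stood at 0.62 and 1.03. RPS15A lost its call in 2 of the 11 fits that left out a library (edgeR adjusted p up to 0.056). Of 40 oxidative phosphorylation genes 15 fell, 20 with p adjusted over the list alone, with a median of -0.52 (camera adjusted p = 3.71e-05; adjusted p = 0.838 with an estimated correlation, and camera adjusted p = 0.627 with a length trend removed and 0.621 without DMSO library 1). COX6C changed by -1.51 (SE 0.23) and NDUFA1 by -1.21 (SE 0.27), the latter not called in 3 of the 11 fits that left out a library (edgeR adjusted p up to 0.109). These lists hold short genes, and the short genes of the library set moved with them. In protein-coding genes with an effective length under 500 bases, the median deviation from wild-type DMSO was -1.019, -0.351 and -0.992 log2 in birinapant libraries 1, 2 and 3. In the 2 DMSO libraries it was 0.383 and -0.383.

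**Figure D3:**
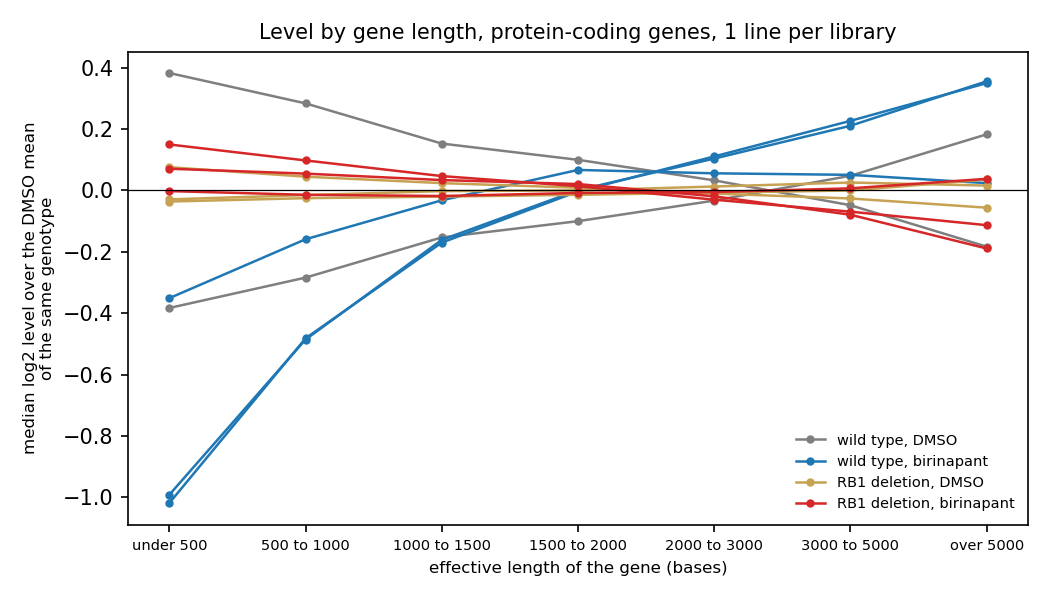
Median log2 deviation of each library from the DMSO mean of its genotype, by class of effective gene length in bases, with 1 line per library. Wild-type birinapant libraries 1 and 3 ran from -1.019 and -0.992 in genes under 500 bases to 0.35 and 0.356 in the longest length class.

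Outside the lists, the vitamin A transporter gene STRA6 (1.76, SE 0.26), the kinesin gene KIF12 (1.76, SE 0.19) and the laminin gene LAMB3 (1.44, SE 0.18) rose in wild type. The fatty acid receptor gene CD36 changed by -2.28 (SE 0.30) and MGP, which encodes matrix Gla protein, by -1.78 (SE 0.21). CYP19A1 and MUC16 passed at -2.27 and -2.06, but without wild-type DMSO library 2 they stood at -0.95 (edgeR adjusted p = 0.342) and -0.09 (edgeR adjusted p = 0.889). EdgeR called 2311 genes in wild type, 1121 higher and 1190 lower, of which 445 changed at least 2-fold. A fit of the 5 wild-type libraries alone called 0 genes at the same threshold, with 2743 at an unadjusted p under 0.05, and left BIRC3 at 2.25 (edgeR adjusted p = 0.0625); DESeq2 on all groups called 3106. Leaving out wild-type birinapant library 3 left 427 calls and library 1 left 480, whereas leaving out library 2 gave 3557 and DMSO library 2 gave 3980.

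The responses of both genotypes shared 30 of the genes that rose, where independent lists of 1121 and 56 genes would share 3.79. The shared genes included BIRC3, MAP3K14, NFKB2, RELB, TNFAIP3, NFKBIA, ICAM1, UBD, OASL, STAT1 and TAP1. No gene was called lower in both, since none was called lower in RB1-deletion cells in the fit of all groups. A fit of the RB1-deletion libraries alone did call lower genes, as given above. Of the 56 genes, 52 had a positive log2 fold change in wild type, and the median was 1.3 in RB1 deletion and 0.7 in wild type. Since the genes were selected on their RB1-deletion values, larger values there follow in part from the selection. Across all tested genes, which are not independent replicates, the log2 fold changes had Pearson r = 0.07 and Spearman rho = 0.065. The contrasts share no library.

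**Figure D4:**
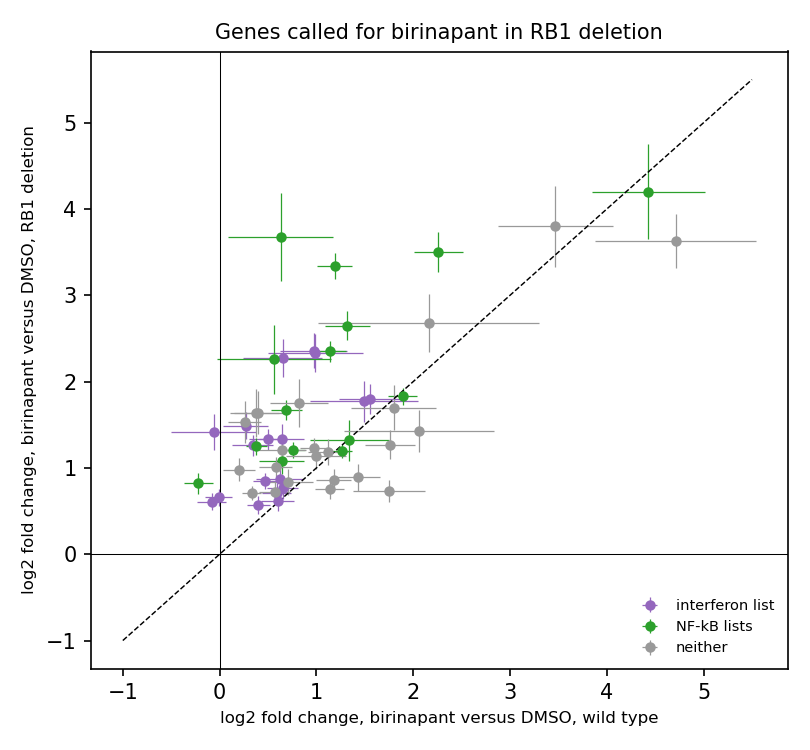
Log2 fold change after birinapant in wild type (horizontal) against RB1 deletion (vertical) for the 56 genes called in RB1 deletion, with 1 point per gene. In 52 of the 56 genes the wild-type value was above 0, and in 44 the RB1-deletion value was the larger, in genes selected on their RB1-deletion values.

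The test of the difference between the responses, RB1 deletion minus wild type, gave 12 genes, 9 of them positive. TNFAIP3 responded more in RB1-deletion cells, by 2.15 log2 (SE 0.24; edgeR adjusted p = 0.00939), and was the only one of the 56 genes to pass. Its treated levels were close, at 21.4 ± 3.52 CPM in RB1 deletion and 19.1 ± 2.31 CPM in wild type (SD, n = 3 each). The DMSO levels were 2.11 ± 0.183 CPM (SD, n = 3) and 8.37 ± 0.604 CPM (SD, n = 2), a baseline difference that coincides with library series. Of 32 NF-kB targets 6 were higher and 13 lower in RB1-deletion DMSO, also with p adjusted over the list alone (camera adjusted p = 0.236, or 0.0491 without wild-type DMSO library 2). The difference for TNFAIP3 no longer passed without RB1-deletion DMSO library 2 (edgeR adjusted p = 0.0507) or 3 (edgeR adjusted p = 0.0602), or without wild-type birinapant libraries 1 and 3 (edgeR adjusted p = 0.149). Nor did it pass with the replicate number as a block (edgeR adjusted p = 0.477), with voom weights per genotype (limma adjusted p = 0.0983) or with limma-trend on TPM (1.08; limma adjusted p = 0.0608). BIRC3 differed by 1.24 (SE 0.37; edgeR adjusted p = 0.101), RELB by 1.33 (SE 0.30; edgeR adjusted p = 0.0842) and IFIT1 by 1.39 (SE 0.43; edgeR adjusted p = 0.107), none past the threshold. NFKB2 differed by -0.06 (SE 0.14). MGP (1.96), the trefoil factor gene TFF3 (1.42) and S100A10 (1.08) fell in wild type, with RB1-deletion values of 0.18, -0.14 and -0.01. The adenylate cyclase gene ADCY5 (-1.23) and the kinesin gene KIF1A (-0.83) rose in wild type, with RB1-deletion values of -0.06 and -0.03. The genes that fell had effective lengths of 594, 498 and 508 bases, and those that rose 4922 and 6429. With a length trend per library removed, 6 of the 12 genes were still called. TNFAIP3 (2.30; edgeR adjusted p = 0.00217), YPEL5 (0.88; edgeR adjusted p = 0.0148) and ADCY5 (-0.91; edgeR adjusted p = 0.036) were among them. MGP (1.46; edgeR adjusted p = 0.0574), TFF3 (0.73; edgeR adjusted p = 0.176), S100A10 (0.39; edgeR adjusted p = 0.24) and KIF1A (-0.49; edgeR adjusted p = 0.0921) were not.

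Over the interferon list the median difference was 0.61 and over the NF-kB targets 0.31, with camera adjusted p-values of 4.36e-09 and 0.0045. With an estimated correlation the adjusted p-values were 0.655 and 0.835, and without wild-type DMSO library 1 the NF-kB targets did not pass (camera adjusted p = 0.293). With p adjusted over the list alone, 18 of 48 interferon genes differed, and among NF-kB targets 9 positive and 1 negative, against 0 and 1 over all genes. The non-canonical NF-kB list had a median of -0.06 (camera adjusted p = 0.894), with 2 positive and 2 negative members when p was adjusted over the list alone. The number of genes was unstable: it was 2900 without wild-type DMSO library 2, 1048 without DMSO library 1, 1806 without wild-type birinapant library 2 and 1 to 3 without any other library. DESeq2 called 1464.

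RB1-deletion libraries in DMSO differed from wild type in RNA classes as well as in protein-coding genes, with 3436 genes higher and 4199 lower by edgeR. All 18 tested replication-dependent histone genes were lower, with a median of -6.43 (camera adjusted p = 3.09e-16; adjusted p = 0.228 with an estimated correlation), and 18 of 18 with p adjusted over the list alone. H1-2 changed by -4.96 (SE 0.21) and H2BC21 by -3.41 (SE 0.24). Of 89 genes of small RNA types 88 were lower. Their median was -8.72, or -5.92 with the 46 genes at 0 counts in RB1 deletion set to the floor. The RNA components of RNase MRP, RMRP (-13.94, SE 0.59), and of telomerase, TERC (-11.08, SE 0.30), were among the lowest. The mitochondrial ribosomal RNAs MT-RNR2 (9.13, SE 0.96) and MT-RNR1 (8.20, SE 0.95) were higher.

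Among protein-coding genes, p53 targets were higher in RB1-deletion libraries. In DMSO 24 of 33 passed, 25 with p adjusted over the list alone, and none was lower (camera adjusted p = 1.09e-08; adjusted p = 0.00987 with an estimated correlation). CDKN1A, which encodes the cell-cycle inhibitor p21, was higher by 1.81 (SE 0.13), GDF15 by 1.04 (SE 0.11), EDA2R by 1.61 (SE 0.26) and MDM2, the p53 ubiquitin ligase gene, by 0.52 (SE 0.13). Cholesterol synthesis genes were higher in 17 of 24 cases, 18 with p adjusted over the list alone, among them INSIG1 (1.5, SE 0.12) and SQLE (1.15, SE 0.10), with a camera adjusted p of 9.76e-07 and an adjusted p of 0.408 with an estimated correlation. Of 51 E2F targets and replication genes 12 were higher and 2 lower, 11 and 2 with p adjusted over the list alone, and the median was 0.16. This list had a camera adjusted p of 0.0226, an adjusted p of 0.762 with an estimated correlation, 0.684 without wild-type DMSO library 2 and 0.287 with a length trend removed. E2F1 (0.20, SE 0.12) and CCNE2 (-0.02, SE 0.15) did not pass, and RFC4 stood at -1.11 (SE 0.18), or at 1.2 on the TPM scale, below the median of all genes on that scale, 2.03.

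Marker genes of several epithelial and stromal kinds were also higher in RB1-deletion DMSO libraries. Among 20 mesenchymal genes 8 were higher and 2 lower, also with p adjusted over the list alone. COL3A1, a fibrillar collagen gene, stood at 3.97 (SE 0.15) and LOXL2 at 3.63 (SE 0.23). VIM, at 0.39 (SE 0.37), did not pass. Among 18 basal markers 10 were higher and 4 lower, also with p adjusted over the list alone. CAV1 stood at 2.09 (SE 0.17), and COL17A1, at -1.94 (SE 0.73), was among those lower. Among 20 luminal markers 12 were higher and 3 lower, 13 and 3 with p adjusted over the list alone, with the keratin genes KRT8 at 0.94 (SE 0.12) and KRT18 at 0.88 (SE 0.11). Their camera adjusted p-values were 0.00831, 0.00831 and 0.00247, and with an estimated correlation the adjusted p-values were 0.173, 0.616 and 0.213. Without wild-type DMSO library 1 the basal list had an adjusted p of 0.36. Of 59 ribosomal protein genes 49 were lower, 53 with p adjusted over the list alone, with a median of -0.87 (camera adjusted p = 2.05e-08; adjusted p = 0.616 with an estimated correlation). With a length trend removed the list no longer passed (camera adjusted p = 0.408). In birinapant 1 was higher and 1 lower, 0 and 1 with p adjusted over the list alone, with a median of 0.06 (camera adjusted p = 0.199, or 6.96e-05 without wild-type birinapant library 2). RPS21 changed by -2.41 (SE 0.27) but stood at 0.04 on the TPM scale. BIRC3 was lower by -2.67 (SE 0.33; edgeR adjusted p = 7.31e-05) and by -0.04 on the TPM scale, while BIRC2 was higher by 0.55 (SE 0.14) and XIAP by 0.64 (SE 0.16). PCDH10, a protocadherin gene, went from 0.983 to 68.4 CPM (6.10, SE 0.17), COL12A1 was higher by 4.83 (SE 0.29) and DIO2 by 4.69 (SE 0.28). CYP19A1, which encodes aromatase, was at 0 in RB1-deletion DMSO, at least 60.2-fold lower, or at least 24.3-fold without wild-type DMSO library 2 and 96.1-fold without library 1. The read-through gene SYNJ2BP-COX16, which overlaps its parent genes, was at 0 in wild-type DMSO and at least 15.5-fold higher. On the TPM scale the median of all genes moved to 2.03 log2 above wild type, and 14037 genes were called higher and 557 lower.

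In birinapant, as in DMSO, RB1-deletion libraries had higher p53 targets and interferon-stimulated genes. In DMSO 13 of 48 interferon genes were higher and 3 lower, 11 and 3 with p adjusted over the list alone, with a median of 0.24 (camera adjusted p = 0.0217; adjusted p = 0.616 with an estimated correlation). That call was lost without wild-type DMSO library 2 (camera adjusted p = 0.17) or RB1-deletion DMSO library 2 (camera adjusted p = 0.0774). Of 33 p53 targets 28 were higher and none lower, 29 with p adjusted over the list alone (camera adjusted p = 1.38e-11; adjusted p = 0.00393 with an estimated correlation). CDKN1A was higher by 1.73 (SE 0.11), EDA2R by 2.39 (SE 0.24) and the death receptor gene FAS by 1.58 (SE 0.13). Of the interferon genes in birinapant 33 were higher and 2 lower, 35 and 2 with p adjusted over the list alone, with a median of 0.81. MX1 stood at 2.80 (SE 0.27), IFIT1 at 1.83 (SE 0.22) and STAT1 at 1.15 (SE 0.11). The camera adjusted p was 5.14e-10, and the adjusted p was 0.189 with an estimated correlation.

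Cholesterol synthesis genes were higher in 17 of 24 cases under birinapant and lower in 1, also with p adjusted over the list alone (camera adjusted p = 2.46e-06; adjusted p = 0.346 with an estimated correlation). STARD4 stood at 2.25 (SE 0.23) and SC5D at 1.37 (SE 0.11). All 18 histone genes were lower, also with p adjusted over the list alone, with a median of -5.60 (camera adjusted p = 1.39e-16; adjusted p = 0.189 with an estimated correlation). Of 51 E2F targets 4 were higher and 9 lower, 2 and 5 with p adjusted over the list alone (camera adjusted p = 0.828). BIRC3 remained lower, by -1.43 (SE 0.17), but stood at 0.13 on the TPM scale. EdgeR called 3001 genes higher and 3774 lower in birinapant, with PCDH10 at 5.94 (SE 0.14) and the guidance factor gene SLIT2 at 4.04 (SE 0.16). On the TPM scale the median of all genes moved to 1.35 log2.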

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

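The tests of depth, of a length trend and of a shared spread as explanations were chosen only after the result was seen.

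The drug response differed between genotypes for 12 genes in edgeR's test of the difference, RB1 deletion minus wild type. TNFAIP3 differed by 2.15 log2, MGP by 1.96, TFF3 by 1.42, S100A10 by 1.08 and YPEL5 by 0.86. ADCY5 differed by -1.23 and KIF1A by -0.83. The pseudogenes RPL22P1 and RPS3AP6, at 2.01 and 1.37, share sequence with ribosomal protein genes, so their counts are uncertain. The other 3 genes had no symbol. With a length trend removed, 6 of the 12 were still called, and MGP, TFF3, S100A10, RPS3AP6 and KIF1A were not. Over lists, the difference had camera adjusted p-values of 4.36e-09 for interferon genes, 0.0045 for NF-kB targets, 8.07e-22 for ribosomal proteins, 8.17e-07 for oxidative phosphorylation, 0.000694 for replication-dependent histones and 0.0142 for E2F targets. With an estimated correlation the adjusted p-values were 0.655 for interferon genes and 0.835 for each of the other lists named. With the length trend removed, 3 of the 6 lists were still called, and oxidative phosphorylation (camera adjusted p = 0.566) and E2F targets (0.129) were among those that were not. Without wild-type DMSO library 1, 3 of the 6 were still called, and NF-kB targets, oxidative phosphorylation (0.293 each) and histones (0.367) were not. E2F targets were not called without wild-type DMSO library 2 (0.41, with the direction turned) or birinapant library 2 (0.135).

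The larger interferon and NF-kB response in RB1-deletion libraries was weighed over all 89 tested members of the interferon, NF-kB target and non-canonical NF-kB lists, whose median difference was 0.32 log2 (0.14 without wild-type DMSO library 1 to 0.44 without DMSO library 2). A length trend in the libraries would shrink the difference on its removal, but it was 0.35 (0.28 to 0.42 with a library left out), which argues against length. Thinning the RB1-deletion libraries to wild-type depth gave 0.44 over 81 members (0.17 to 0.49 with a library left out), from 0.32 over the same members. The difference did not shrink at equal total depth. However, thinning left the differences of all genes tested both ways about as they were (slope 0.95 over 14706 genes). It moved the values too little to decide on depth. A different response of cells with the RB1 deletion remains a hypothesis. In the main fit 1 of the 89 members passed the difference test, but this count was unstable. It was 11 with the length trend removed, 20 without wild-type birinapant library 2, and 0 without RB1-deletion DMSO library 2 or 3. Such a response cannot be told apart from the library series, because the series and the genotype coincide in all 11 libraries.

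Birinapant in wild type gave many called genes, with ribosomal protein genes lower. Over all 10 tested members of the non-canonical NF-kB list the median was 0.59 log2 (0.56 to 0.65 with a library left out), and still 0.59 (0.55 to 0.68) with a length trend per library removed, which argues against length as the cause of that rise. With the trend removed, the median of the ribosomal protein list was -0.17 (-0.22 to -0.11), from -0.86 (-1.15 to -0.48), so a length difference between libraries is a candidate explanation for the shared fall. The trend was fitted on genes that include these, so a real fall could itself be removed in part. With the trend removed, 32 of 59 members were called, counted in either direction (16 without birinapant library 3 to 35 without birinapant library 2). Of the 59, 16 were positive. The fit of the 5 wild-type libraries alone called 0 genes with edgeR (2743 at an unadjusted p under 0.05; DESeq2 on all groups called 3106), so the number of calls may rest on a spread shared with the quieter RB1-deletion libraries. A drug effect on ribosomal protein genes remains open.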

How the results depend on the processing

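Tests on protein-coding genes only, with the length trend removed, with thinned libraries, with voom weights or without wild-type birinapant libraries 1 and 3 were chosen only after the results were seen. Unless a cause is named, the cause was not tested.

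Of 2311 genes called for birinapant in wild type, 445 passed a 2-fold threshold. The count was 0 with only the groups compared (2743 at an unadjusted p under 0.05; DESeq2 3106), 201 with voom weights, 7096 with limma-trend on TPM and 6 without libraries 1 and 3, a setting with fewer samples. In the fit of wild type alone MAP3K14 was 1.87 (edgeR adjusted p = 0.0625), NFKB2 1.25 (0.0679), RELB 1.30 (0.182) and TNFAIP3 1.18 (0.164). Leaving out 1 library gave 427 (birinapant 3) to 3980 (DMSO 2), with 480 for birinapant 1 and 3557 for birinapant 2.

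Of the 56 genes in RB1 deletion, all remained among the 156 called with no filter, 232 with only the groups compared, 121 with DESeq2, 105 with the length trend removed and 234 with voom weights, while limma-trend on TPM called 31. Leaving out 1 library gave 33 (RB1-deletion birinapant 3) to 120 (wild-type DMSO 2), with 117 for wild-type DMSO 1, 35 for RB1-deletion DMSO 1 and birinapant 2, and 34 for RB1-deletion DMSO 3. The death receptor list had a camera adjusted p of 0.0663 without RB1-deletion DMSO 3 and 0.0744 without birinapant 3, and PPP1R15A an edgeR adjusted p of 0.0513 without DMSO 3. STAT1 had edgeR adjusted p-values of 0.0859 without wild-type birinapant 1, 0.212, 0.103 and 0.228 without RB1-deletion DMSO 1, 2 and 3, and 0.205 and 0.221 without RB1-deletion birinapant 2 and 3.

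The difference of the responses gave 12 genes, 1435 with no filter, 24 with a filter of 1 CPM, 1464 with DESeq2, 2050 with limma-trend on TPM, 69 with protein-coding genes only, 336 with the length trend removed (6 of the 12 among them), 2 with voom weights (TNFAIP3 limma adjusted p = 0.0983) and 0 without libraries 1 and 3 (edgeR; 1411 at an unadjusted p under 0.05). Leaving out 1 library gave 1 (RB1-deletion DMSO 2 or 3) to 2900 (wild-type DMSO 2), with 1048 for wild-type DMSO 1, 1806 for wild-type birinapant 2, 3 for wild-type birinapant 3, and 2 for wild-type birinapant 1, RB1-deletion DMSO 1 and each RB1-deletion birinapant library. The difference for TNFAIP3 had an edgeR adjusted p of 0.0507 without RB1-deletion DMSO 2, 0.0602 without DMSO 3, 0.149 without wild-type birinapant 1 and 3 and 0.477 with the replicate number as a block, and a limma-trend adjusted p of 0.0608 on TPM.

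RB1 deletion against wild type gave 7635 genes in DMSO and 6775 in birinapant, of which 3120 and 2535 passed a 2-fold threshold. Limma-trend on TPM called 14594 and 13980. With 1 library left out the counts were 6281 to 7852 and 5255 to 8371. The median of all genes in DMSO was -0.061 with TMM and -0.103 with upper-quartile factors. On the TPM scale it was 2.03 in DMSO and 1.35 in birinapant, 0.61 for the drug in wild type and -0.66 for the difference. The RB1 level relative to wild-type DMSO was 1.21 in wild-type birinapant, 0.6 in RB1-deletion DMSO and 0.555 in RB1-deletion birinapant in CPM, and 2.64, 3.51 and 3.08 in TPM.

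The overlap of 30 genes became 14 with a 2-fold threshold, 51 with the length trend removed and 12 with voom weights. Leaving out 1 library gave 15 (wild-type birinapant 1) to 57 (wild-type DMSO 1), with 50 for wild-type DMSO 2, 17 for wild-type birinapant 3 and RB1-deletion DMSO 1, and 18 for RB1-deletion DMSO 2 and 3 and birinapant 2 and 3.

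Lists called by camera numbered 13 and 12 for RB1 deletion in DMSO and birinapant, 9 and 15 for the drug in wild type and RB1 deletion, and 6 for the difference. With an estimated correlation they numbered 1, 1, 0, 6 and 0, and with fry 8 for the drug in RB1 deletion and 0 for the difference. Protein-coding genes only gave 7 in DMSO and 5 for the drug in wild type, and removal of the length trend gave 7 in DMSO. With 1 library left out, in this order, the counts were 10 to 13, 11 to 13, 6 to 10, 12 to 16 and 5 to 7. For the difference, 3 of the 6 lists were among the 7 called without wild-type DMSO 1, and 3 were among the 4 called with the length trend removed.

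The replicate numbers gave no sign of pairing. Deviations of same-numbered libraries from their group means correlated at -0.53 and -0.64 in wild type and at 0.18, -0.44 and 0.18 in RB1 deletion. Only 1 of 3 RB1-deletion libraries correlated best with its own number. With groups of 2 or 3 libraries, where the 2 wild-type DMSO deviations mirror each other, this cannot show that the samples were unpaired. With the replicate number as a block, 4 genes were called for the drug in wild type, 20 in RB1 deletion and 0 for the difference (edgeR; 1606 at an unadjusted p under 0.05; DESeq2 without the block 1464), and the overlap was 0.

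Directions turned mainly on the TPM scale, where the medians of all genes are those given above. For RB1 deletion in DMSO, limma-trend on TPM gave RB1 1.71, CCNE2 2.28, RFC4 1.2, POLE2 1.43, COL17A1 0.18, RPL3 2.47, RPL4 2.93, RPS21 0.04, RPL34 0.85, RPS15A 1.02 and RPS27A 1.17. In birinapant it gave RB1 0.25, BIRC3 0.13, E2F1 1.36, RFC4 0.97, E2F2 0.82 and POLE2 0.86. For the drug in wild type it gave RPL3 0.62 and RPL4 1.03, and for the difference YPEL5 -0.12 and RPL3 -0.6. The effective length offset gave RPL4 0.44 in DMSO and XIAP -0.08 in birinapant. Removal of the length trend gave RPL4 0.21 in DMSO and RPS27 0.01 for the drug. Leaving out 1 library put CCNE2 in DMSO between -0.29 (without wild-type DMSO 2) and 0.36 (without wild-type DMSO 1). The E2F list's camera adjusted p ran from 7.25e-08 to 0.684 in DMSO and from 3.6e-12 to 0.41 for the difference, lowest without wild-type DMSO 1 and highest, with the direction turned, without wild-type DMSO 2.

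Among the named gene results, calls were lost in 61 with the block, 48 without wild-type birinapant libraries 1 and 3 (24 stayed on their side of the threshold), 42 with only the groups compared, 39 with voom weights, 25 with limma-trend on TPM, 17 with the effective length offset, 11 with the length trend removed and 7 with thinned libraries. DESeq2 lost none and gained 10. On simulated counts with 1 spread per gene for all libraries, 22.4% of 1.5-fold changes were recovered for the drug in wild type. For the drug in RB1 deletion 44.8% were, so in that simulation changes of that size were mostly not detected. The separate spread of each genotype was not simulated.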

Other observations

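The tests of histone variants with a poly(A) tail, of small RNA types and of the E2F list for S phase were chosen only after the result was seen. Death receptor genes also differed between genotypes in both treatments, and BCL2 family and lysosome genes in birinapant, while mitotic genes as a list did not pass. In DMSO 11 of 20 death receptor genes were higher and 3 lower, also with p adjusted over the list alone (camera adjusted p = 0.0211; adjusted p = 0.192 with an estimated correlation). Of 28 lysosome and autophagy genes 13 were higher and 3 lower in DMSO, 13 and 5 with p adjusted over the list alone (camera adjusted p = 0.0439; adjusted p = 0.616 with an estimated correlation). That list lost its call in 8 of the 11 fits that left out a library (camera adjusted p up to 0.107, without wild-type DMSO library 2). The BCL2 family, with 7 and 2 of 18, also with p adjusted over the list alone, did not pass (camera adjusted p = 0.082). In birinapant 10 of the death receptor genes were higher and 3 lower in RB1-deletion libraries, 12 and 4 with p adjusted over the list alone (camera adjusted p = 0.0108; adjusted p = 0.135 with an estimated correlation). Of the BCL2 family genes 9 were higher and 2 lower, 9 and 3 with p adjusted over the list alone (camera adjusted p = 0.0124; adjusted p = 0.135 with an estimated correlation). Of the lysosome and autophagy genes 10 were higher and 3 lower, 11 and 3 with p adjusted over the list alone (camera adjusted p = 0.00499; adjusted p = 0.404 with an estimated correlation). Of 45 mitotic genes 1 was higher and 8 lower, 1 and 5 with p adjusted over the list alone, with a median of -0.10 (camera adjusted p = 0.449; adjusted p = 0.969 with an estimated correlation). In DMSO the mitotic list had a median of -0.03 (camera adjusted p = 0.885). There wild-type DMSO libraries 1 and 2 lay at 0.228 and -0.228 log2 from their mean. The list's direction was up without library 1 and down without library 2.

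Of the 56 genes that rose in RB1-deletion cells, 18 lay in none of the lists. Chosen after their values were seen, they included KLHDC7B (3.63 log2, SE 0.31), the complement gene CFB (1.64, SE 0.28), the calcium-binding protein gene S100A9 (1.53, SE 0.24) and the transcription factor gene SOX9 (0.89, SE 0.16). In wild type CFB and S100A9, at 0.38 and 0.26, did not pass, while SOX9 rose by 1.43 (SE 0.23). The difference was 1.25 for CFB (edgeR adjusted p = 0.0993) and 1.27 for S100A9 (edgeR adjusted p = 0.0852), so neither response was shown to differ. For the drug in wild type, 2 of 20 mesenchymal genes rose, 0 with p adjusted over the list alone, with a median of 0.33 (camera adjusted p = 0.0243; adjusted p = 0.31 with an estimated correlation, and camera adjusted p = 0.258 without wild-type DMSO library 1). Immune cell and endothelial markers, with 7 and 6 genes tested, passed camera in no contrast with all libraries, but immune cell markers passed for the drug in RB1 deletion in 7 of the 11 fits that left out a library (camera adjusted p down to 0.00581, without RB1-deletion DMSO library 3).

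RNAs without a poly(A) tail were nearly missing from the RB1-deletion libraries. Fewer cells in S phase after RB1 deletion would leave small RNA types, which are made throughout the cycle, about unchanged, but 88 of 89 were called lower in DMSO, which argues against that explanation for them. A different selection of RNA before sequencing predicts that histone variants with a poly(A) tail keep their level, and the median of 10 such genes was 0.11 (SD 0.53) in DMSO, against -6.43 for the replication-dependent histones. This goes with a selection of RNA by its poly(A) tail in these libraries, although the labels name 1 total RNA kit. Selection of coding RNA was not tested. The replication-dependent histones encode proteins and were low, but which genes such a selection would cover is not given. How the libraries were made stays open, as does any other effect of the RB1 deletion, and for the histone genes fewer cells in S phase: the E2F median was 0.16 (SD 0.31), but loss of RB1 is itself expected to raise E2F targets, and the list's direction turned without wild-type DMSO library 2.

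The 6 libraries of a comparison allow 10 splits into 3 and 3, too few for a share under 0.05. For birinapant in RB1 deletion the real split gave 56 genes and 15 lists, and the highest other splits gave 0 and 9, so that 1 split reached each real value. For RB1 deletion against wild type in birinapant the real split gave 6775 genes and 12 lists, and the highest others gave 0 and 11, again with 1 split as large.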
